A study of Mus musculus with 24 samples.

How the data were processed

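The series measured RNA by bulk sequencing in punches of frontal cortex from male C57BL/6 mice. Per the labels' protocols, mice of 4 weeks received a daily intraperitoneal injection for 28 days. The 4 groups received vehicle, sarcosine (100 mg/kg), memantine (20 mg/kg) or both drugs, here called the combination. Each group has 6 libraries, 24 in all, and the labels name neither a batch nor a date. Library numbers in the labels run by group, so if they follow the order of processing, an effect of that order would coincide with the groups.

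The deposited table gives 1 normalised signal per gene and library, which its values show to be the authors' read count divided by a size factor for each library. Per the submitters' processing notes, the reads were handled with FastQC, STAR, featureCounts 1.6.0 and DESeq2 1.42.1 on the mouse build mm39; the notes give neither the order of the steps nor their filters. The unit was checked on the values. In each library every value was a whole multiple of a single step, within 0.01 of a whole read, for 100% of values, and the largest distance from a whole read was 5.16e-05. In memantine replicate 5 that step lay near 1. Dividing by the step gave back whole reads, 12678114 to 21844579 per library.

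Of 57180 genes, the 16578 with a value of at least 10 in at least 6 libraries were tested. Values were transformed to log2(value + 1). A linear model of the 4 group means over all 24 libraries was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, no covariate), and tests were two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 counted as called. A total of 6 contrasts were read from this fit: 5 between groups and the interaction, which is combination minus memantine minus the difference of sarcosine from vehicle. The p-values measure the spread between samples, since the labels do not say more about the animals than the sample titles.

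A total of 34 gene lists for pathways, cell types and sex-linked genes were tested with camera in limma at an inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and beside it with a correlation estimated per list and with fry. Members called over all genes and members called after adjustment over the list alone were counted. List scores per library (the mean of centred log2 values) and other measures per library were compared by exact two-sided permutation tests of 6 against 6 libraries; their 924 arrangements allow no p under 0.00216, and 50 such tests formed the family of the library measures. A further 2 lists, for olfactory bulb and for MHC class I presentation, were written after the data had been seen.

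Main tests, lists and the rule for named genes were fixed before the data were examined. The rule takes genes with a mean of at least 50 that were called: the 10 highest and 10 lowest fold changes in each comparison against vehicle and in combination against sarcosine, and the 5 highest and 5 lowest in combination against memantine and the interaction. Where few passed in a direction, genes with the smallest p fill up to 5 or 3 and are given as values. It adds up to 4 members with the smallest p of each described list, and Grin1, Grin2a, Grin2b, Slc6a9, Sardh, Gnmt and Pipox against vehicle. Predicted genes were counted and not named. The lists described for each comparison were chosen after their results were seen.

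Transcript length and GC content were those of the longest transcript of each gene in GENCODE vM21. They were matched by gene identifier for 16287 of the tested genes (98.2%). The build of GENCODE vM21 differs from mm39, and no coordinates were used. A gene expressed mainly as a shorter transcript would be corrected as if it were longer. For the length correction, added after the data had been seen, a loess trend (span 0.3) of each library on log10 length and GC content was removed. The pipeline was tested on simulated counts with the depths of the 24 libraries and 200 genes changed in the sarcosine libraries. In them 44% of genes changed by 0.5 (log2) and 77% of those changed by 1 were called. Of 132 calls, 8.33% were unchanged genes. Simulated genes varied independently, while the first principal component held 45.6% of the real variance, so these shares may not hold for the real data. With a simulated length trend, 55.0% of 291 calls were unchanged genes before the correction and 4.10% of 122 after it. That trend was linear in the same log10 length and equal in all sarcosine libraries, so it may be easier to remove than the real one.

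Alternatives covered the pseudocount, the filter, the scaling, the libraries in the fit, a replicate block, library weights, list scores as covariates, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the length correction, thinned reads and subsets of libraries. No library and no sample column was left out of the model of the 4 groups.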

Results

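Frontal cortex RNA was compared between 6 libraries each of mice given vehicle, sarcosine, memantine or both drugs for 28 days. Sarcosine is N-methylglycine, a blocker of the glycine transporter GlyT1 and a co-agonist at the glycine site of the NMDA receptor, and memantine is an open-channel blocker of that receptor. The reads recovered per library numbered 15543738 to 17425235 with vehicle and 17008198 to 21844579 with sarcosine. With memantine they numbered 12678114 to 19714592 and with the combination 14700861 to 15653093. Between 23043 and 25234 genes had reads in a library. The sex-linked genes fitted male mice in every library, with 0 to 4.39 normalised counts of Xist and 891 to 1246 of Ddx3y. Fold changes below are on the log2 scale from limma, with normalised counts as mean ± SD over the 6 libraries of a group.

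Markers of neighbouring brain regions varied between libraries within every group. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, ranged from 3901 to 44936 normalised counts over the 24 libraries. Drd1, the dopamine receptor of striatal neurons, ranged from 126 to 1313, Cdhr1 of the olfactory bulb from 71.2 to 3464, Mbp of myelin from 12037 to 128952 and Ttr of the choroid plexus from 0.897 to 52720. Slc17a7 and Tbr1, a transcription factor of deep cortical layers, were lowest, and Drd1 highest, in sarcosine replicate 1. The first principal component held 45.6% of the variance and the second 10.7%. The first correlated with these markers: Mbp at r = 0.919, Drd1 at 0.824 and Ttr at 0.780. Its correlation was -0.813 with Slc17a7, -0.701 with Tbr1 and -0.783 with Cdhr1. Mitochondrial transcripts took 4.79 ± 0.565% of reads with vehicle (SD, n = 6), 3.96 ± 0.351% with sarcosine, 4.23 ± 0.477% with memantine and 4.08 ± 0.345% with the combination (sarcosine against vehicle, exact permutation p = 0.01299, adjusted p = 0.0812).

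Signal also followed transcript length. The slope of a library's log2 deviation on a 10-fold change of length was -0.23 ± 0.096 with vehicle, 0.18 ± 0.15 with sarcosine, 0.064 ± 0.070 with memantine and -0.018 ± 0.18 with the combination (mean ± SD, n = 6). Sarcosine differed from vehicle by 0.41 (exact permutation p = 0.00216, adjusted p = 0.0271 over 50 tests), memantine by 0.29 (exact permutation p = 0.00216, adjusted p = 0.0271) and the combination by 0.21 (exact permutation p = 0.0325, adjusted p = 0.148). The first 2 of these p-values are the smallest the design allows. Across genes, which are not independent replicates, the fold change correlated with log10 length at r = 0.430 for sarcosine, 0.318 for memantine and 0.233 for the combination, each against vehicle.

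**Figure D1:**
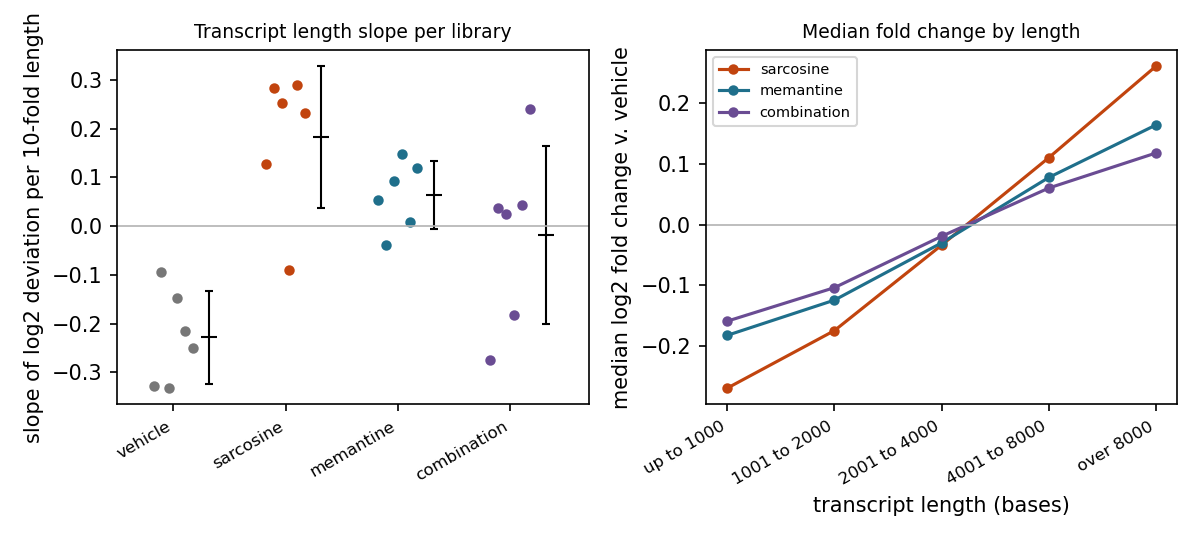
Left, slope of the log2 deviation of signal per 10-fold transcript length in each library (points) with the mean and SD of the 6 libraries of a group; right, median log2 fold change against vehicle of genes in 5 bins of transcript length in bases. The vehicle mean was -0.23 and the sarcosine mean 0.18, and the median fold change for sarcosine ran from -0.27 in the shortest bin to 0.26 in the longest.

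The comparison of sarcosine with vehicle asks what the glycine transport blocker changes alone. mRNAs for ribosomes and for the respiratory chain were lower with sarcosine. Of 60 measured cytosolic ribosomal protein genes, 49 fell (59 adjusted over the list alone), and of 63 nuclear genes for oxidative phosphorylation subunits, 39 fell (50 adjusted over the list alone). Among 44 genes with recurrent autism-associated variants, 16 rose (24 rose and 2 fell adjusted over the list alone). In the cholesterol pathway 8 of 22 genes fell (12 adjusted over the list alone), and of 16 microglial markers 6 fell (9 adjusted over the list alone). Striatal markers had a median of 0.63 (camera adjusted p = 0.00407; adjusted p = 0.8296 with an estimated correlation; exact permutation p of the score 0.331), with 0 of 21 called. Markers of vascular smooth muscle and leptomeningeal cells had a median of -0.43 (camera adjusted p = 0.0243; adjusted p = 0.8296 with an estimated correlation; exact permutation p 0.294), with 0 of 16 called.

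Rps18, a protein of the small ribosomal subunit, fell from 2288 ± 202 normalised counts with vehicle to 1711 ± 122 with sarcosine, a fold change of -0.42 (SE 0.069, adjusted p = 0.00152). Rpl41 changed by -0.46 (adjusted p = 0.00152), Rpl38 by -0.41 (adjusted p = 0.00152) and Rps14 by -0.41 (adjusted p = 0.00298). The ribosomal list had a median of -0.34 (camera adjusted p = 1.89e-33, and 0.228 with an estimated correlation). After the length correction it was -0.15 (camera adjusted p = 2.14e-25 at a correlation of 0.01), with a score difference of -0.16 (exact permutation p = 0.00866). Cox4i1, a subunit of cytochrome c oxidase, fell from 8007 ± 750.3 to 6156 ± 264 normalised counts, by 0.38 on the log2 scale (adjusted p = 0.00152). Uqcr11 of the cytochrome b-c1 complex changed by -0.50 (adjusted p = 0.00152), and of the ATP synthase subunits Atp5f1e changed by -0.50 (adjusted p = 0.00152) and Atp5pf by -0.33 (adjusted p = 0.00173). The oxidative phosphorylation list had a median of -0.32 (camera adjusted p = 8.62e-28, and 0.228 with an estimated correlation). After the length correction it was -0.14 (camera adjusted p = 4.43e-10 at a correlation of 0.01). Its score then differed by -0.13 between the libraries, which did not pass (exact permutation p = 0.106). All 8 of these genes lay below the vehicle mean in 6 of 6 sarcosine libraries. Their transcripts are short, and the length correction ended the calls of Rpl38 (-0.15, adjusted p = 0.206), Rps14 (-0.20, 0.101), Uqcr11 (-0.25, 0.108), Cox4i1 (-0.14, 0.468) and Atp5pf (-0.14, 0.419).

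Adnp, a chromatin-associated homeobox protein, rose from 73.6 ± 8.38 to 135 ± 24.9 normalised counts, by 0.86 (SE 0.17, adjusted p = 0.00322). Ash1l, a histone methyltransferase, rose by 0.54 (adjusted p = 0.00258), Mbd5, a methyl-CpG-binding domain protein, by 0.42 (adjusted p = 0.00295) and Tcf20, a transcriptional coregulator, by 0.39 (adjusted p = 0.00336), each in 6 of 6 libraries. The autism gene list had a median of 0.25 (camera adjusted p = 4.03e-11; adjusted p = 0.228 with an estimated correlation). The length correction reduced it to 0.068 (adjusted p = 0.00551). The call of Adnp held after it (0.75, adjusted p = 0.0207) and those of Ash1l (0.30, adjusted p = 0.0527), Mbd5 (0.21, adjusted p = 0.188) and Tcf20 (0.20, adjusted p = 0.202) did not. Among cholesterol enzymes, the sterol reductase Tm7sf2 fell by 0.52 (SE 0.089, adjusted p = 0.00152), and farnesyl diphosphate synthase, Fdps, changed by -0.42 (adjusted p = 0.00418). The mevalonate pathway kinases Pmvk and Mvk changed by -0.39 (adjusted p = 0.00178) and -0.36 (adjusted p = 0.00381). Their list had a median of -0.21 (camera adjusted p = 2.56e-06; adjusted p = 0.228 with an estimated correlation) and -0.20 after the length correction. Tm7sf2 was still called after it (-0.51, adjusted p = 0.0162), and Fdps (-0.40, adjusted p = 0.0527), Mvk (-0.27) and Pmvk (-0.19) were not. In microglia, the complement genes C1qa and C1qb changed by -0.33 (adjusted p = 0.03002) and -0.32 (adjusted p = 0.0169). The lipid receptor Trem2 changed by -0.35 (adjusted p = 0.0245) and the selectin ligand Selplg by -0.32 (adjusted p = 0.0149). The microglial list had a median of -0.26 (camera adjusted p = 2.81e-05; adjusted p = 0.253 with an estimated correlation) and -0.13 after the length correction (adjusted p = 0.00171). Trem2 was still called after it (-0.44, adjusted p = 0.0379), and Selplg (-0.25), C1qa (-0.11) and C1qb (-0.11) were not. The correction took the longest annotated transcript, 4784 bases for Trem2 and 3083 for Tm7sf2. Which transcripts these samples express was not tested.

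The fold changes farthest from 0 included interferon-induced GTPases. Gbp4 rose from 58.8 ± 20.7 to 169 ± 64.9 normalised counts, by 1.504 (SE 0.26, adjusted p = 0.00153), and Gbp5 by 1.08 (adjusted p = 0.0177); both have close copies in the genome, so their counts are uncertain. The heparan sulfate sulfotransferase Hs6st3 rose by 1.25, the potassium channel Kcnh5 by 1.24, the soluble guanylate cyclase subunit Gucy1a2 by 1.23. The Golgi sodium-proton exchanger Slc9a7 rose by 1.12, the clustered protocadherin Pcdhb16 by 0.96, and Klhl11, Plcxd3 and Zkscan16 by 0.96, 0.95 and 0.94. Cortistatin, the interneuron neuropeptide encoded by Cort, fell from 141 ± 35.98 to 67.2 ± 32.3 normalised counts, by 1.20 (SE 0.32, adjusted p = 0.0196). Lower values were also called for the transcriptional regulator Prdm8 (-0.82), the cytochrome oxidase subunit Cox6a2 (-0.77), and the G protein subunit Gng13 (-0.73). The C-type natriuretic peptide precursor Nppc fell by 0.70, the retinol carrier Rbp4 by 0.69, the organelle biogenesis gene Bloc1s1 by 0.63, the histone variant H2aj by 0.62, the trafficking gene Trappc6a by 0.60 and Olfml3 by 0.59. Each of these 20 genes lay on its side of the vehicle mean in 6 of 6 sarcosine libraries, except Gucy1a2 and Prdm8 in 5 of 6. The length correction ended 11 of the 20 calls, those of Kcnh5 (1.18 after it), Gbp5 (1.04), Plcxd3 (0.88), Cort (-0.95), Prdm8 (-0.89), Cox6a2 (-0.55), Nppc (-0.53), Rbp4 (-0.50), Gng13 (-0.48), Bloc1s1 (-0.38) and Trappc6a (-0.38).

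Of the genes closest to the drug's own chemistry, 1 was called, Gcsh. Grin1, the obligatory NMDA receptor subunit, had 5426 ± 868 normalised counts with vehicle and 5589 ± 976 with sarcosine (0.038, SE 0.11, adjusted p = 0.905). Grin2a differed by 0.049 (adjusted p = 0.958) and Grin2b by 0.26 (adjusted p = 0.319); none of the 3 was called. Slc6a9, which encodes GlyT1, had a fold change of 0.30 (adjusted p = 0.437), sarcosine dehydrogenase (Sardh) -0.028 (adjusted p = 0.9102), the sarcosine oxidase Pipox 0.37 (adjusted p = 0.755) and glycine N-methyltransferase (Gnmt) 0.096 (adjusted p = 0.948). No member of the list of 13 NMDA receptor genes was called (median 0.12, camera adjusted p = 0.0682; adjusted p = 0.448 with an estimated correlation). Of these, 12 had positive values, and their score was 0.15 above vehicle (exact permutation p = 0.0281, adjusted p = 0.0957; fry adjusted p = 0.06299). The smallest p among them were those of the amino acid transporter Slc38a2 (0.31, adjusted p = 0.149), the auxiliary subunit Neto2 (0.32, adjusted p = 0.1998) and Grin3a (0.24, adjusted p = 0.322). Of 27 genes of sarcosine, glycine, serine and one-carbon metabolism, Gcsh of the glycine cleavage system fell by 0.34 (adjusted p = 0.0208) and, after the length correction, was at -0.22 (adjusted p = 0.114). The values of methionine synthase Mtr (0.24, adjusted p = 0.0544), Dld (0.11, adjusted p = 0.306) and Shmt1 (-0.35, adjusted p = 0.334) were not called. That list had a median of -0.049 (camera adjusted p = 0.688).

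In all, 782 genes were higher and 766 lower with sarcosine (3698 at an unadjusted p under 0.05, where 829 are expected by chance); with upper-quartile scaling the split was 603 to 1177. After the length correction 187 genes passed, 82 higher and 105 lower, 165 of them among the 1548 and 15 of them among the 41 genes named above as called. In the 15 libraries with a low olfactory bulb score, 4 of them sarcosine and 4 vehicle, 49 passed, 9 higher and 40 lower, and of the named genes Cox4i1, H2aj and Uqcr11 did.

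Memantine against vehicle asks what the receptor blocker changes alone. The 2 genes called were clock genes. Per3, a period gene of the circadian feedback loop, rose from 441 ± 89.8 normalised counts with vehicle to 690.3 ± 41.4 with memantine, a fold change of 0.67 (SE 0.11, adjusted p = 0.0155). Nr1d2, which encodes the clock repressor REV-ERB beta, rose from 1162 ± 95.8 to 1692 ± 99.7, by 0.54 (SE 0.071, adjusted p = 0.00144). Both lay above the vehicle mean in 6 of 6 libraries. Per3 and Nr1d2 were also called higher with sarcosine against vehicle, at 566 ± 49.9 and 1412 ± 108 normalised counts with sarcosine. The combination had 603 ± 83.9 and 1479 ± 159, also called higher, so the rise was not particular to memantine. No time of day of collection entered the model, so whether it differed between groups was not tested. Of 19 circadian genes, 2 rose (8 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 1.90e-09; adjusted p = 0.133 with an estimated correlation). The values of Per2 (0.95, adjusted p = 0.0753) and Per1 (0.87, adjusted p = 0.0908) were not called.

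The ribosomal protein list had a median of -0.23 with memantine (camera adjusted p = 3.01e-28; adjusted p = 0.326 with an estimated correlation) and -0.11 after the length correction (adjusted p = 2.95e-16); 0 of 60 were called over all genes and 53 were lower adjusted over the list alone. The oxidative phosphorylation list had a median of -0.19 (camera adjusted p = 2.45e-18; adjusted p = 0.342 with an estimated correlation) and -0.051 after the length correction (adjusted p = 0.00401), with 0 of 63 called over all genes and 33 lower adjusted over the list alone.

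Microglial markers had a median of -0.30 with memantine (camera adjusted p = 5.06e-10; adjusted p = 0.133 with an estimated correlation); 0 of 16 were called over all genes and 10 were lower adjusted over the list alone. The values of Trem2 were 324 ± 38.8 with vehicle and 232 ± 9.08 with memantine (-0.48, adjusted p = 0.0753). Those of the integrin Itgam, of C1qa and of Siglech differed by -0.43 (adjusted p = 0.0817), -0.37 (adjusted p = 0.102) and -0.31 (adjusted p = 0.113). Heat shock and unfolded protein response genes had a median of 0.25 (camera adjusted p = 1.61e-06; adjusted p = 0.342 with an estimated correlation), with 0 of 22 called over all genes and 8 higher adjusted over the list alone. Their smallest p belonged to the chaperone Hspa1a (0.69, adjusted p = 0.0817), whose reads are uncertain because of its copy Hspa1b. Next were the endoplasmic reticulum chaperone Hspa5 (0.54, adjusted p = 0.105), Herpud1 (0.32, adjusted p = 0.109) and Pdia4 (0.51, adjusted p = 0.113). Immediate early genes, which neuronal activity induces, had a median of 0.53 (camera adjusted p = 2.39e-06; adjusted p = 0.597 with an estimated correlation), 0 of 25 called over all genes and 2 higher adjusted over the list alone. Klf4 differed by 0.86 (adjusted p = 0.128), Sik1 by 0.58 (adjusted p = 0.198) and Atf3 by 0.89 (adjusted p = 0.214).

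The memantine target genes were not called: Grin1 differed by 0.046 (adjusted p = 0.912), Grin2a by 0.10 (adjusted p = 0.926) and Grin2b by 0.15 (adjusted p = 0.713). Their list had a median of 0.077 (camera adjusted p = 0.451). Slc38a2 (0.32, adjusted p = 0.249), Grin2c (-0.20, adjusted p = 0.567), Slc6a9 (0.22, adjusted p = 0.697) and Slc1a4 (-0.081, adjusted p = 0.712) had its smallest p. Sardh (0.020), Pipox (-0.00152) and Gnmt (0.57) were not called either. The genes next in p with higher values were the splicing helicase Dhx15 (0.32) and the nucleoporin Ahctf1 (0.38), with an adjusted p of 0.0753 each. With lower values they were the secreted neudesin gene Nenf (-0.39), the succinate dehydrogenase assembly factor Sdhaf1 (-0.45), Mtln (-0.32), the tubulin cofactor Tbcc (-0.43) and the lysosomal protein Laptm5 (-0.30), with adjusted p from 0.06105 to 0.0753.

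At an unadjusted p under 0.05, 2441 genes passed, where 829 are expected; DESeq2 called 430 genes and edgeR 3. The split was 3 higher to 19 lower with upper-quartile scaling and 2 to 10 with quantile normalisation. After the length correction Nr1d2 was called (0.49, adjusted p = 0.00674) and Per3 was not (0.57, adjusted p = 0.0784). In the libraries with a low olfactory bulb score limma called 0 genes (1787 unadjusted).

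The combination against vehicle asks what differed when both drugs were given. A ceramide enzyme, a lipocalin and a glucose transporter were among the higher genes. Acer2, an alkaline ceramidase, rose from 93.2 ± 26.6 normalised counts with vehicle to 292 ± 71.1 with the combination, by 1.64 (SE 0.19, adjusted p = 0.000158), above the vehicle mean in 6 of 6 libraries. Lcn2, the iron-siderophore carrier lipocalin of reactive glia and inflamed tissue, rose from 13.6 ± 11.04 to 453 ± 324, by 4.21 (SE 0.93, adjusted p = 0.0427), in 5 of 6 libraries, and its combination libraries spread widely. Slc2a1, the glucose transporter of the blood-brain barrier, rose by 0.75 (adjusted p = 0.0455), and Serpina3n, a protease inhibitor of reactive astrocytes, by 1.09 (adjusted p = 0.0427), each in 6 of 6.

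Of 19 glucocorticoid-responsive genes, 2 rose (6 adjusted over the list alone), with a median of 0.72 (camera adjusted p = 1.17e-10; adjusted p = 0.348 with an estimated correlation). The glucocorticoid receptor co-chaperone Fkbp5 had 573 ± 106 normalised counts with vehicle and 1390.0 ± 727 with the combination (1.13, adjusted p = 0.0586). The kinase Map3k6 differed by 1.40 (adjusted p = 0.0762), and neither was called. Of 15 inflammatory and reactive glia genes, Serpina3n and Lcn2 rose (2 adjusted over the list alone; median 0.45, camera adjusted p = 0.00692; adjusted p = 0.491 with an estimated correlation). The values of Steap4 (1.54, adjusted p = 0.207) and Cd14 (0.73, adjusted p = 0.405) were not called. Among 19 circadian genes, Nr1d2 rose by 0.35 (adjusted p = 0.0427) and Per3 by 0.47 (adjusted p = 0.0455), with 5 called adjusted over the list alone. The values of Ciart (0.85, adjusted p = 0.0837) and Nr1d1 (0.48, adjusted p = 0.0982) were not called over all genes. The circadian median was 0.15 (camera adjusted p = 0.000208; adjusted p = 0.3603 with an estimated correlation). Of the 63 oxidative phosphorylation genes, Uqcr11 (-0.37, adjusted p = 0.0448) and Uqcrq (-0.34, adjusted p = 0.0455) fell, and 36 were lower adjusted over the list alone. The values of Ndufs7 (-0.29, adjusted p = 0.0568) and Ndufs8 (-0.25, adjusted p = 0.0583) were not called. That list had a median of -0.19 (camera adjusted p = 1.85e-20; adjusted p = 0.3603 with an estimated correlation). Striatal markers had a median of 0.48 (camera adjusted p = 0.00237; adjusted p = 0.8803 with an estimated correlation; exact permutation p of the score 0.255), with 0 of 21 called. Markers of vascular smooth muscle and leptomeningeal cells had a median of -0.52 (camera adjusted p = 0.00169; adjusted p = 0.638 with an estimated correlation; exact permutation p 0.229), with 0 of 16 called.

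Other called genes with higher values were the focal adhesion protein Tns2 (0.78), the minor spliceosome component Rnpc3 (0.59), Fnbp4 (0.41), the histone methyltransferase Setd1a (0.40) and the histone demethylase Kdm3a (0.40), with adjusted p from 0.0427 to 0.0455. Dpysl2, a microtubule-binding protein of growing axons, fell from 5086 ± 400.4 to 3682 ± 475 normalised counts, by 0.47 (SE 0.078, adjusted p = 0.0178). The microglial receptor Gpr34 fell by 0.72, the fructose transporter Slc2a5 by 0.66, the galectin Lgals1 by 0.58 and the membrane progestin receptor Paqr7 by 0.55. The ribonuclease subunit Rnaseh2c fell by 0.50, Eef1akmt1 by 0.41, Prxl2b by 0.41, the cytochrome oxidase assembly factor Coa6 by 0.41 and sepiapterin reductase, Spr, by 0.40. These 15 genes lay on their side of the vehicle mean in 6 of 6 combination libraries. Grin1 (0.023), Grin2a (0.0118), Grin2b (-0.059), Slc6a9 (0.16), Sardh (-0.17), Pipox (0.79) and Gnmt (0.68) were not called.

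In all, 23 genes were higher and 67 lower (2361 at an unadjusted p under 0.05), with 17 to 15 when libraries were scaled to equal totals; DESeq2 called 499 and edgeR 70. The length correction left 5 genes, among the named ones Acer2 (1.59, adjusted p = 0.000254) and Dpysl2 (-0.53, adjusted p = 0.00675). A fit of the 2 groups alone called 1, the libraries with a low olfactory bulb score 1, reads thinned to the shallowest library 31, and the fit without sarcosine replicate 1 called 55.

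**Figure D2:**
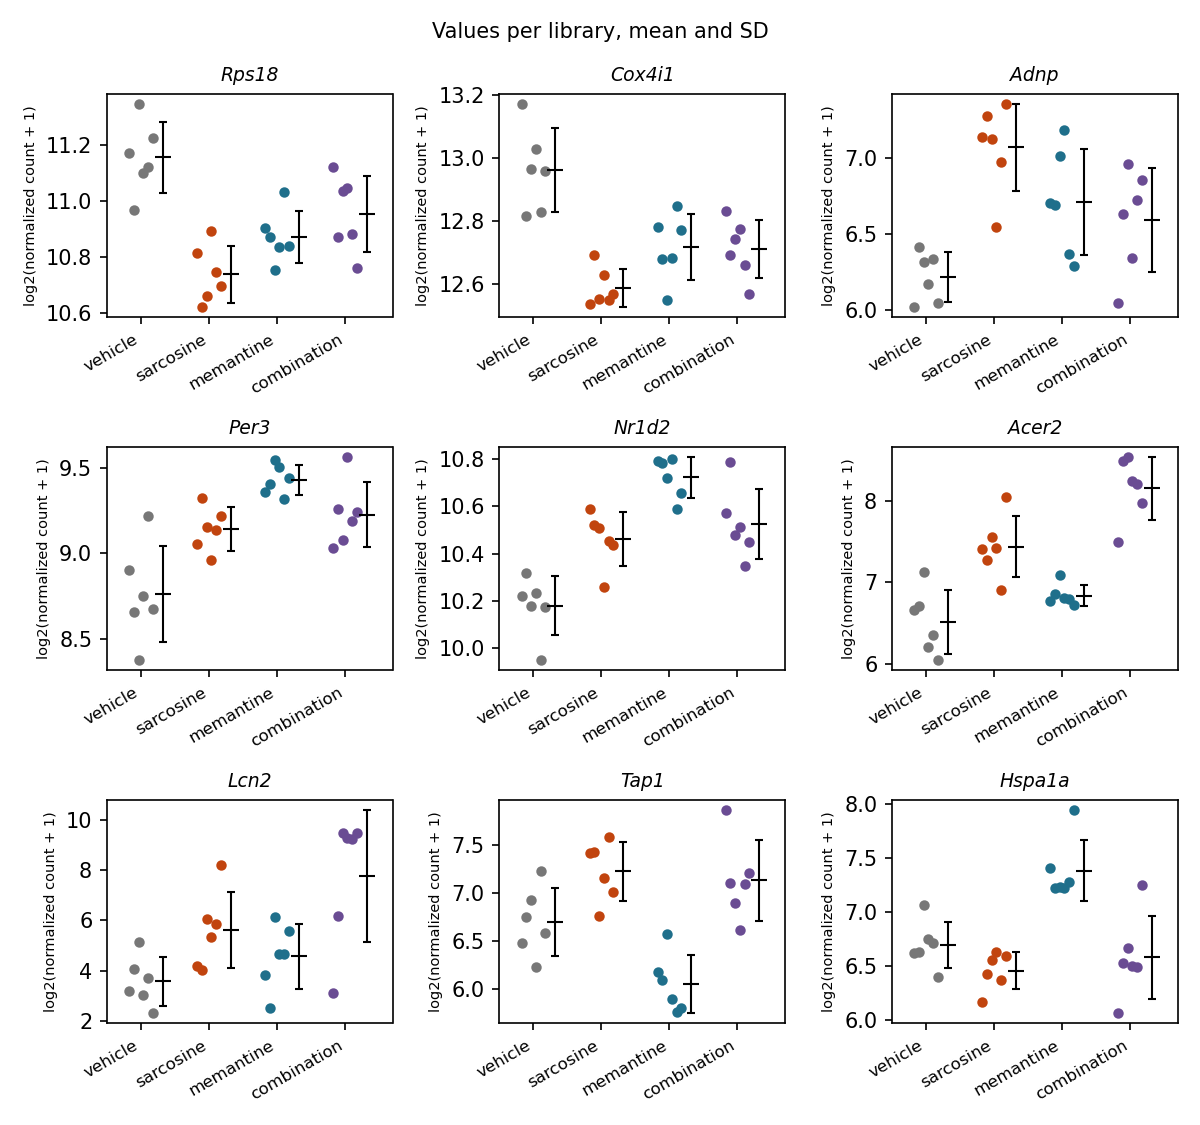
Values of 9 genes per library (points) as log2(normalised count + 1), with the mean and SD of the 6 libraries of each group. Rps18 and Cox4i1 were lower and Adnp higher with sarcosine than with vehicle (-0.42, -0.38 and 0.86), Per3 and Nr1d2 were highest with memantine, and Acer2 was highest with the combination (292 ± 71.1 normalised counts).

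The combination against sarcosine shows what memantine changed in mice that received sarcosine. No gene differed by limma (0 called, 1443 at an unadjusted p under 0.05); edgeR called 0 and DESeq2 45. The ribosomal protein genes had a median of 0.15 (camera adjusted p = 4.11e-20; adjusted p = 0.524 with an estimated correlation), with 0 of 60 called over all genes and 0 adjusted over the list alone. Rps18 had 1711 ± 122 normalised counts with sarcosine and 1987 ± 186 with the combination (0.21, adjusted p = 0.362). The genes Rps7 (0.24, adjusted p = 0.337), Rpl22 (0.23, adjusted p = 0.3495) and Rps14 (0.24, adjusted p = 0.372) had similar values. Glucocorticoid-responsive genes had a median of 0.57 (camera adjusted p = 2.40e-09; adjusted p = 0.49997 with an estimated correlation), with 19 of 19 values positive, 0 called over all genes and 6 higher adjusted over the list alone. The NMDA receptor list had a median of -0.082 (camera adjusted p = 0.0263; adjusted p = 0.49997 with an estimated correlation), with 0 of 13 called and 0 adjusted over the list alone. Markers of endothelial cells and pericytes had a median of -0.15 (camera adjusted p = 0.000505; adjusted p = 0.524 with an estimated correlation), 0 of 18 called and 4 lower adjusted over the list alone. The angiopoietin receptor Tek differed by -0.61 (adjusted p = 0.262), the pericyte gene Rgs5 by -0.33 (adjusted p = 0.3103), the drug efflux pump Abcb1a by -0.41 (adjusted p = 0.3504) and the vascular growth factor receptor Kdr by -0.83 (adjusted p = 0.3504).

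Of the remaining genes with the smallest p, higher values with the combination belonged to the mediator subunit Med4 (0.32), the cathepsin Ctsf (0.26), Nop53 (0.27), the polyamine acetyltransferase Sat1 (0.35) and the splicing kinase Clk4 (0.42). Lower ones belonged to Zmym2 (-0.31), Fam20b (-0.27), the chromatin remodeller Bptf (-0.29) and the neurofibromin gene Nf1 (-0.31), all 9 with adjusted p from 0.238 to 0.262.

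For the genes called in sarcosine against vehicle, the question was whether they lay closer to vehicle in the combination. None of the 1548 was called in the opposite direction in combination against sarcosine (limma, 0 genes). In 1480 of them (95.6%) the fold change against vehicle was smaller in the combination than with sarcosine alone, where chance with unchanged groups gave 75.1%. Chance lies above 50% because the genes were selected by their sarcosine values. The chance genes were the 1548 with the largest absolute fold change in a draw, and not genes called by adjusted p. The chance share is a mean over 100 draws without its spread, so whether 95.6% lies beyond chance was not tested. The median ratio of the fold changes was 0.586 for the combination and 0.605 for memantine alone. The sign against vehicle was the same as with sarcosine for 98.7% of the genes in the combination and 98.1% with memantine (77.3% by chance). When the sarcosine libraries were split into 3 and 3 in all 20 ways, calling genes on one part and comparing on the other, the share with a smaller change averaged 85.7% (65.0 to 100), over 17 to 1522 calls. No chance value was computed for this share, and the 75.1% above is not its baseline.

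Across 16578 genes, the fold changes of sarcosine and memantine against vehicle correlated at r = 0.574, but unchanged groups compared with the same vehicle libraries gave 0.491 (covariance 0.0418, simulated 0.0461). With the vehicle libraries split into 3 and 3, r was 0.103 (covariance 0.00849). Sarcosine against vehicle and combination against sarcosine correlated at r = -0.471 (simulated -0.448, split 0.0888; covariance -0.0287, simulated -0.0361). Pairs without shared libraries gave r = 0.0805 for the effect of sarcosine without and with memantine (simulated -0.0308). They gave -0.0778 for the effect of memantine without and with sarcosine (simulated 0.02802). All 4 lay within the range of the 100 simulated draws, and leaving out 1 library turned the sign of each of the latter 2 (from -0.0255 to 0.199 and from -0.231 to 0.0656).

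The combination against memantine shows what sarcosine changed in mice that received memantine. Several of the genes called take part in antigen presentation. Tap1, the peptide transporter for MHC class I, rose from 66.5 ± 15.1 normalised counts with memantine to 144 ± 46.5, by 1.08 (SE 0.19, adjusted p = 0.0367). H2-Q4, an MHC class I gene, rose by 1.25 (adjusted p = 0.0367) and Gbp4 by 1.49 (adjusted p = 0.0314). Acer2 rose from 114 ± 11.04 to 292 ± 71.1 normalised counts, by 1.32 (SE 0.19, adjusted p = 0.00215), and Plek, a substrate of protein kinase C in leukocytes and microglia, by 0.42 (adjusted p = 0.0382). All 5 lay above the memantine mean in 6 of 6 libraries. The other called genes were H2-Q6 (1.81), H2-Q7 (2.32), the interferon-induced GTPase Tgtp2 (1.31) and 1 predicted gene. The genes H2-Q6, H2-Q7 and Tgtp2 stand outside the rule and were chosen after their values were seen. H2-Q, Gbp and Tgtp genes have near-identical copies, so the split of reads between them is uncertain.

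Of 22 heat shock and unfolded protein response genes, 0 were called over all genes and 16 were lower adjusted over the list alone, with a median of -0.39 (camera adjusted p = 9.33e-21; adjusted p = 0.0473 with an estimated correlation). No other list call in the 6 comparisons held with an estimated correlation. Of the 34 lists, fry called 7 for sarcosine, 2 for memantine and 5 for the combination, each against vehicle. It called 0 for the combination against sarcosine, 1 for the combination against memantine and 5 for the interaction. Hspa1a had 169 ± 38.4 normalised counts with memantine and 97.98 ± 28.5 with the combination (-0.80, adjusted p = 0.0593). The values of its copy Hspa1b (-1.03, adjusted p = 0.149), Pdia6 (-0.40, adjusted p = 0.145) and Pdia4 (-0.60, adjusted p = 0.154) were not called either. The prolyl hydroxylase P4ha1 (-0.67, adjusted p = 0.0624) and the co-chaperone Stip1 (-0.32, adjusted p = 0.0729) had the next smallest p among lower values. Immediate early genes had a median of -0.58 (camera adjusted p = 1.00e-07; adjusted p = 0.772 with an estimated correlation), with 0 of 25 called and 0 adjusted over the list alone. The values of Egr1 (-0.98, adjusted p = 0.398), Egr4 (-0.71, adjusted p = 0.421), Nr4a3 (-0.85, adjusted p = 0.472) and Maff (0.85, adjusted p = 0.476) had the smallest p. Of 20 interferon-responsive genes 0 were called and 0 adjusted over the list alone (median 0.21, camera adjusted p = 0.00427; adjusted p = 0.838 with an estimated correlation). Their smallest p belonged to Ifitm3 at 0.64 (adjusted p = 0.529), Trim30a at 0.42 (adjusted p = 0.604), Stat2 at 0.15 (adjusted p = 0.833) and Oasl2 at 0.49 (adjusted p = 0.851). Striatal markers had a median of 0.57 (camera adjusted p = 0.000805; adjusted p = 0.838 with an estimated correlation; exact permutation p of the score 0.251), with 0 of 21 called. Markers of vascular smooth muscle and leptomeningeal cells had a median of -0.31 (camera adjusted p = 0.0296; adjusted p = 0.838 with an estimated correlation; exact permutation p 0.143), with 0 of 16 called.

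In all, 9 genes were higher and 0 lower by limma (1280 at an unadjusted p under 0.05), 10 by edgeR and 61 by DESeq2. The libraries with a low olfactory bulb score gave 4 calls, none among the 9, the fit of the 2 groups alone gave 4 and thinned reads 5. After the length correction 14 passed, 8 of them among the 9.

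The interaction tests whether the sarcosine effect differed between mice with and without memantine. A value opposite in sign to the sarcosine effect means that the estimated effect was smaller, absent or reversed with memantine. The contrast subtracts the sarcosine effect of the same libraries, so genes with a large effect lean to the opposite sign. All 273 interaction calls among the 1548 sarcosine calls had it. Of the 1548, 98.1% had the same sign with memantine as with sarcosine. The contrast therefore does not tell an interaction of the drugs from vehicle libraries that lay apart. Ribosomal protein genes had positive values, and 11 of 60 were called (58 adjusted over the list alone): Rps18 0.50 (SE 0.097, adjusted p = 0.0261), Rpl38 0.46 (adjusted p = 0.0297), Rpl41 0.49 (adjusted p = 0.0358) and Rps14 0.51 (adjusted p = 0.03602). Their median was 0.40 (camera adjusted p = 1.96e-34; adjusted p = 0.361 with an estimated correlation), and 0.17 (adjusted p = 1.91e-21) after the length correction. Of the 44 autism-associated genes, 4 had called negative values (14 adjusted over the list alone): the postsynaptic scaffold Shank3 -0.60 (adjusted p = 0.0328), Tcf20 -0.48 (adjusted p = 0.0381), Adnp -0.97 (adjusted p = 0.0431) and the histone methyltransferase Kmt2c -0.57 (adjusted p = 0.04698). That list had a median of -0.26 (camera adjusted p = 1.21e-10; adjusted p = 0.361 with an estimated correlation), and -0.092 (adjusted p = 0.0335) after the correction.

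The clock gene Per2 had 544 ± 151 normalised counts with vehicle, 798 ± 194 with sarcosine, 1027 ± 144 with memantine and 672 ± 162 with the combination, an interaction of -1.19 (adjusted p = 0.0322). Negative values were also called for the kinase Sik2 (-1.23), Slc9a7 (-1.16), the transcription factor Klf12 (-1.09) and Aff2 (-1.09). Positive ones were called for Znhit2 (0.73), the complex III assembly factor Uqcc3 (0.65), Chrac1 (0.63) and the microglial receptor genes Trem2 (0.63) and Fcer1g (0.60), all 9 with adjusted p from 0.0267 to 0.0447.

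In all, 96 genes had positive and 205 negative interactions (2782 at an unadjusted p under 0.05; 931 by DESeq2 and 256 by edgeR). The split was 130 to 132 with equal totals, 343 to 132 with upper-quartile scaling and 178 to 122 with quantile normalisation. The fold changes followed transcript length here too (r = -0.398 across genes), and after the length correction limma called 0 genes (1423 unadjusted). The libraries with a low olfactory bulb score gave 1 call, the test of all genes without a filter 0 (3542 unadjusted), and the fit without sarcosine replicate 1 gave 83.

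**Figure D3:**
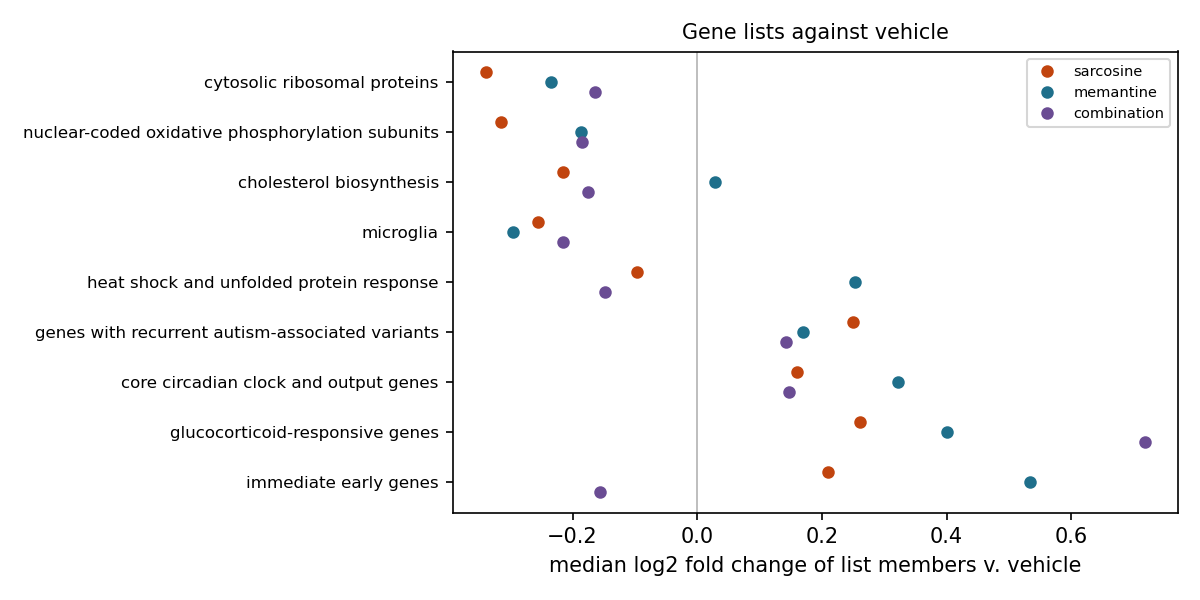
Median log2 fold change against vehicle of the measured members of 9 gene lists, for sarcosine, memantine and the combination (points). Ribosomal protein genes had medians of -0.34, -0.23 and -0.16, and glucocorticoid-responsive genes of 0.26, 0.40 and 0.72.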

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

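The length correction was chosen after the relation of signal to length had been seen. A library stood apart when its gap to the nearest of the other 5 took more of the group's range than Dixon's 95% limit allows. This held in 42 of 724 groups of named genes, list scores and library measures (5.80%), and chance marks about 1 in 20.

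In the vehicle group, the gap as a share of the range was 0.684 for Kcnh5 (replicate 1), 0.775 for Bptf (replicate 1), 0.639 for Trim30a (replicate 1) and 0.676 for Plcxd3 (replicate 2). Further shares among the vehicle libraries were 0.661 for Cort (replicate 3), 0.641 for Fkbp5 (replicate 3), 0.696 for the score of AMPA, kainate and metabotropic glutamate receptors (replicate 3) and 0.727 for the score of glucocorticoid-responsive genes (replicate 3). The vehicle libraries also gave shares of 0.824 for the score of neuropeptides of the cortex (replicate 3), 0.655 for Fnbp4 (replicate 5), 0.889 for Clk4 (replicate 5) and 0.6997 for Ndufs8 (replicate 5).

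In the sarcosine group, the gap as a share of the range was 0.737 for Slc9a7 (replicate 4), 0.794 for Klhl11 (replicate 4), 0.649 for Laptm5 (replicate 4) and 0.712 for Ctsf (replicate 4). Further shares among the sarcosine libraries were 0.627 for Abcb1a (replicate 4), 0.646 for Trem2 (replicate 6), 0.642 for Steap4 (replicate 6) and 0.705 for Cd14 (replicate 6). The sarcosine libraries also gave shares of 0.631 for Sardh (replicate 6).

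In the memantine group, the gap as a share of the range was 0.626 for Aff2 (replicate 2), 0.642 for Acer2 (replicate 3), 0.670 for Fkbp5 (replicate 3) and 0.6703 for the score of glucocorticoid-responsive genes (replicate 3). Further shares among the memantine libraries were 0.705 for Itgam (replicate 4), 0.6497 for the number of reads (replicate 4), 0.652 for Zkscan16 (replicate 5) and 0.776 for Laptm5 (replicate 5). The memantine libraries also gave shares of 0.671 for Atp5pf (replicate 5), 0.741 for Hspa1a (replicate 6) and 0.636 for Pmvk (replicate 6).

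In the combination group, the gap as a share of the range was 0.711 for H2-Q4 (replicate 1), 0.735 for Gnmt (replicate 2), 0.681 for the score of inflammatory and reactive glia genes (replicate 2) and 0.696 for Tek (replicate 3). Further shares among the combination libraries were 0.714 for the score of endothelial cells and pericytes (replicate 3), 0.744 for Fam20b (replicate 4), 0.656 for Prdm8 (replicate 5) and 0.7895 for Ctsf (replicate 6). The combination libraries also gave shares of 0.674 for Hspa5 (replicate 6) and 0.752 for Pdia6 (replicate 6).

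The second kind of result is a sarcosine effect that differed between mice with and without memantine, by the interaction in limma (adjusted p under 0.05). It held for 39 of 143 named genes and for 301 of the 16578 tested genes. Some named genes were chosen by their interaction or sarcosine values, so the 2 shares are not comparable. The positive differences (log2) were Znhit2 0.73, Uqcc3 0.65, Chrac1 0.63, Trem2 0.63, Fcer1g 0.60, Sdhaf1 0.56 and C1qa 0.52. Next among the positive differences were Rps14 0.51, Nenf 0.51, Rps18 0.50, Rpl41 0.49, Atp5f1e 0.48, C1qb 0.47 and Mtln 0.46. Smaller positive differences were Rpl38 0.46, H2aj 0.45, Rps7 0.42, Rpl22 0.40, Nop53 0.39 and Cox4i1 0.37. The negative differences (log2) were Sik2 -1.23, Per2 -1.19, Slc9a7 -1.16, Klf12 -1.09, Aff2 -1.09, Klhl11 -1.03 and Pcdhb16 -0.98. Next among the negative differences were Adnp -0.97, Shank3 -0.60, Per3 -0.58, Ahctf1 -0.57, Kmt2c -0.57, Tcf20 -0.48 and Nr1d2 -0.48. Smaller negative differences were Bptf -0.48, Zmym2 -0.43, Nf1 -0.40, Dhx15 -0.38 and Fam20b -0.29. Their adjusted p ran from 0.0261 to 0.0479, and the length correction ended all of these calls (limma called 0 genes for the interaction after it, 1423 at an unadjusted p under 0.05). Rps18 went from 0.50 to 0.27, Trem2 from 0.63 to 0.71, Adnp from -0.97 to -0.86 and Sik2 from -1.23 to -1.10.

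These differences stand beside a relation of fold changes to transcript length, which may be technical in part. With every library thinned to the shallowest, the sarcosine against vehicle fold change still correlated with length across genes (r = 0.421, against 0.430 before). The number of reads counted therefore does not make the relation by itself. Random thinning keeps the expected ratios within a library, so it cannot test a bias from how the deeper libraries were made. After the correction 187 genes passed for sarcosine against vehicle, and the highest of the 99 other splits gave 1. The ribosomal score went from -0.33 to -0.16 (exact permutation p = 0.00866, not adjusted). As far as a loess trend captures it, a length bias between libraries is not the whole source of these differences. A length bias that the trend left in would follow the groups too, so these tests cannot tell it from another difference. The oxidative phosphorylation score went from -0.27 to -0.13 (exact permutation p = 0.106) while the spread of the libraries did not shrink (SD 0.052 and 0.15 before, 0.074 and 0.17 after), and a length bias stays open as the whole source there. Sarcosine itself, a difference in RNA quality and the order of processing, which follows the groups if library numbers do, also stay open.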

How the results depend on the processing

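The length correction, its use with the striatal score, the olfactory bulb covariate, the libraries with a low olfactory bulb score, thinned reads and the fit without sarcosine replicate 1 were chosen after seeing the data. Counts of calls moved as follows; the cause was not tested unless stated. The main counts were 1548 for sarcosine and 2 for memantine, 90 for the combination against vehicle, 0 against sarcosine, 9 against memantine and 301 for the interaction.

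Sarcosine against vehicle gave 989 with no filter, 980 with only the groups compared, 3149 with quality weights. It gave 2539 and 3275 with the oligodendrocyte and striatal covariates, 187 with the length correction, 877 with the correction and the striatal score, and 49 in the libraries with a low olfactory bulb score, where fewer samples enter. Memantine against vehicle gave 22 with upper-quartile scaling, 12 with quantile normalisation, 421 with quality weights, 112 and 155 with the covariates. It gave 430 with DESeq2, 1 with the length correction, 4 with the correction and the striatal score, 4 with the olfactory bulb covariate and 0 in the libraries with a low score (limma, 1787 unadjusted).

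The combination against vehicle gave 12 with no filter, 154 with a stricter one, 32 with equal totals, 1 with only the groups compared, 328 with quality weights. With the oligodendrocyte, striatal and olfactory bulb covariates it gave 441, 854 and 137, and 499 with DESeq2. It gave 5 with the length correction, 166 with the correction and the striatal score, 1 in the libraries with a low score, 31 with thinned reads and 55 without sarcosine replicate 1. Against sarcosine it gave 27 with quality weights, 6 and 3 with the oligodendrocyte and striatal covariates, 45 with DESeq2 and 1 with the length correction and the striatal score. Against memantine it gave 4 with no filter, 5 with a stricter one, 4 with only the groups compared, 30 with quality weights, 28 and 16 with those covariates. It gave 61 with DESeq2, 14 with the length correction, 19 with the correction and the striatal score, 4 in the libraries with a low score and 5 with thinned reads. The interaction gave 0 with no filter (3542 unadjusted), 457 with a stricter one, 475 with upper-quartile scaling, 1516 with quality weights, and 810, 1056 and 173 with the 3 covariates. It gave 931 with DESeq2, 0 with the length correction (1423 unadjusted), 14 with the correction and the striatal score, 1 in the libraries with a low score and 83 without sarcosine replicate 1. Without a filter more genes are tested, which raises adjusted p. A fit of only the groups compared was not run for the interaction, which needs all 4 groups.

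Of 89 calls of named genes, 39 passed with no filter, 24 with the length correction, 48 with the correction and the striatal score and 3 in the libraries with a low olfactory bulb score; no called named gene changed sign under any setting. Of 71 list calls, 1 passed with an estimated correlation. Some list medians took the other sign, in each pair with the striatal covariate and then with the correction and the striatal score. Of lists that did not pass in the main test, choroid plexus and ependyma passed with sarcosine (-1.20, -0.99), with the combination against vehicle (-0.83, -0.70) and against memantine (-0.65, -0.65). In combination against memantine, presynaptic release (0.11, 0.10) and oligodendrocytes (-0.38, -0.39) did too, and oxidative phosphorylation passed at 0.073 in the libraries with a low score. Lists of that comparison that passed in the main test took the other sign without passing: postsynaptic density (0.040, 0.047) and, with the correction and the striatal score, activity-regulated genes (0.015) and ribosomal proteins (-0.010).

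With the replicate number as a block, the counts were 1525, 4, 18, 0, 8 and 131 in the order above, with 63 calls of named genes and 71 of lists. Across all numbers, 18 of 36 pairs of libraries with the same number correlated above 0.1, and 6 of 24 libraries were closest to their own number, where chance gives 4, so the numbers as a whole were not taken to pair the samples. Replicate 5 differed from the other numbers: its 6 pairs correlated at 0.327 to 0.724 (mean 0.561), and its 4 libraries had olfactory bulb scores of 2.46 to 3.53; the cause was not tested. The other settings (pseudocounts of 0.5 and 5 and edgeR among them) kept every count within 1.5 times of the main one or at 0. Depth limits the genes with few reads; at log2 0.5 the simulated comparison found 44% of changed genes.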

Other observations

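The MHC and olfactory bulb lists, the length correction, and the tests of microglial RNA and of the component's variance between groups were chosen after the data had been seen.

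Some lists were called by camera at a correlation of 0.01 in comparisons where they were not described, and not with an estimated correlation. Cholesterol genes were lower in the combination than with memantine (median -0.18, 9 of 22 adjusted over the list alone and 0 over all genes, camera adjusted p = 2.83e-07; adjusted p = 0.298 with an estimated correlation). Inflammatory and reactive glia genes were higher there (median 0.66, 4 of 15 adjusted over the list alone and 0 over all genes, camera adjusted p = 8.11e-06; adjusted p = 0.298 with an estimated correlation). With sarcosine against vehicle, GABA genes had a median of 0.17 (1 of 20 called, camera adjusted p = 0.0234; adjusted p = 0.228 with an estimated correlation). AMPA, kainate and metabotropic glutamate receptor genes had a median of 0.20 (2 of 21 called, camera adjusted p = 0.0405; adjusted p = 0.448 with an estimated correlation). Neither list passed after the length correction (adjusted p = 0.211 and 0.215). With the combination against vehicle, ribosomal protein genes had a median of -0.16 (0 of 60 called over all genes and 18 lower adjusted over the list alone, camera adjusted p = 1.42e-15; adjusted p = 0.491 with an estimated correlation). Microglial markers had a median of -0.22 there (1 of 16 called, camera adjusted p = 5.79e-07; adjusted p = 0.348 with an estimated correlation). With memantine against vehicle, autism genes had a median of 0.17 (0 of 44 called over all genes, 7 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.12e-09; adjusted p = 0.326 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.40 there (0 of 19 called, camera adjusted p = 7.30e-05; adjusted p = 0.609 with an estimated correlation).

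MHC class I presentation genes and interferon-gamma-induced GTPases (28 measured) were higher with the combination than with memantine, with a median of 0.73, 28 positive members and 6 called (camera p = 8.25e-34; p = 0.00154 with an estimated correlation). Their score differed by 0.85 between combination and memantine (exact permutation p = 0.00216, adjusted p = 0.0271). It differed by 0.61 between sarcosine and vehicle (exact p = 0.0216), -0.41 between memantine and vehicle (exact p = 0.0368) and 0.44 between combination and vehicle (exact p = 0.0736); the latter 3 did not pass adjustment over the 50 tests. Against vehicle, 8 members were called higher with sarcosine (median 0.56), 0 with memantine by limma (median -0.39) and 2 with the combination (median 0.34).

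This may be an effect of sarcosine on antigen presentation, found and tested on the same data. The length correction left the list score for the difference from memantine at 0.82 (exact permutation p = 0.00216). Those 2 groups differed little in length slope (-0.082, exact permutation p = 0.333), so this test says little about the length bias. Between sarcosine and vehicle, whose slopes differed by 0.41, the score went from 0.61 to 0.63 after the correction (exact permutation p = 0.0108). As far as a loess trend captures it, the length bias does not account for that difference. The microglial marker score was lower with sarcosine than with vehicle (-0.23, exact permutation p = 0.00866). That argues against more microglial RNA as the source of the higher values with sarcosine against vehicle. Between combination and memantine the microglial score differed by 0.034 (exact permutation p = 0.597), so it was not lower there. Marker levels do not tell the amount of microglial RNA from the state of the cells, so a microglial source stays open. Reads shared between near-identical copies stay open for the list as a whole, although Tap1, which has no such copy, rose by 1.08 between memantine and the combination. The order of processing stays open too.

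The first principal component did not follow treatment: 1.52% of its variance lay between groups (permutation p = 0.955).

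Other splits of the same libraries were drawn 100 at a time, the real one included. For sarcosine against vehicle 1 of 100 splits gave as many calls as the real 1548 (highest other 836), for memantine 1 gave as many as 2 (highest other 1). For the combination against vehicle 2 gave as many as 90 (highest other 506), and against memantine 3 gave as many as 9 (highest other 1662). For the interaction 1 gave as many as 301 (highest other 0). Its splits shuffled all 24 libraries and so removed every difference between groups. A count above them can come from any group that lies apart, and not only from an interaction. With each comparison taken alone, chance is unlikely to give each of these 5 counts. Chance is not excluded, as 100 splits allow no share under 1 in 100 and the shares were not adjusted over the comparisons. For the combination against sarcosine the real count was 0 (limma, 1443 unadjusted; highest other 679), which all 100 splits reach whatever the data, so these splits say nothing about chance. Counts of 506 and 1662 in other splits, several times the real ones, point to a structure of the samples that the groups do not follow.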
